A study of Mus musculus with 29 samples.

How the data were processed

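Bulk RNA sequencing was done on 29 libraries of sorted CD8 T cells from mouse spleen in 2 experiments, each with its own table. Per the labels' protocols, RNA was taken with an AllPrep micro kit, cDNA was made with the SMART-Seq v4 kit and libraries with Nextera XT, a preparation that keeps no strand information. The submitters' processing notes name HISAT2 2.0.5, featureCounts, Subread, DESeq2 and the mm10 build, with no role or order; the annotation release and the settings are not given in the sources used here. The deposited tables hold the authors' raw count of reads for each Ensembl gene ID, whole numbers with no scaling. Reads of overlapping antisense genes cannot be told apart in such counts. Reads that match close paralogs alike, such as some of receptor V segments or granzymes, may be lost or given to the wrong gene. No molecular identifiers were used per the labels' protocols, so PCR copies count as reads, and intervals and floors cover counting error only.

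Each table listed 55487 gene IDs, of which 55141 had a symbol in GENCODE M21 (GRCm38, mm10), the source of the coordinates, given from 1. IDs with no symbol held at most 0.0768% of a library's counts, and genes left out of the tests at most 0.0996%. Mitochondrial transcripts made up 0.278% to 0.814% of counts in the time course and 0.306% to 0.871% in the strain experiment, and the 10 most abundant genes 4.541% to 6.517% and 4.788% to 5.686%. At day 5.5 the mitochondrial share was 0.507% to 0.605% in stem-like and 0.278% to 0.408% in TD libraries. At day 48 it was 0.598% to 0.814% and 0.328% to 0.362%. In the strain experiment the ranges of stem-like and TD libraries overlapped. Libraries were grouped by their labels alone. The labels do not say what the numbers of the libraries stand for, and the main fits have no block. In expression, correlations between libraries of the same number lay above 0.1 in 2 of 22 pairs, a set that includes pairs across days or infections. The 2 were stem-like and TD pairs of the time course, at 0.12 at day 5.5 and 0.14 at day 48. Stem-like and TD libraries of other numbers had at most 0.05 and 0.07 there. V segment shares, checked after the results were seen, went with the number in the time course. Deviations of Trbv shares in stem-like and TD libraries of the same number had r 0.24 to 0.71 at day 5.5 and 0.49 to 0.75 at day 48, and at most 0.13 and 0.01 for other numbers. Trav shares did so at day 48 (0.23 to 0.52, others at most 0.01) and in Arm (0.28 to 0.79, others at most 0.25), and less so at day 5.5 (0.06 to 0.39, others at most 0.09). Trbv shares had 0.06 to 0.27 in Cl13 (others at most 0.41) and 0.00 to 0.63 in Arm (others at most 0.46), and Trav shares -0.13 to 0.10 in Cl13 (others at most 0.24). The labels do not say whether such libraries come from the same mice. All 28 pairs of replicates differed by more than sampling noise, with median chi-square ratios of 7.23 to 28.3. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples, which may be technical. In the time course it is not technical alone if the V segment shares that follow the number stem from the mice, which was not tested.

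Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, leaving 15544 in the time course and 15507 in the strain experiment, scaled with TMM (factors 0.864 to 1.137 and 0.949 to 1.081) and fitted with one mean per group in a robust quasi-likelihood model for each table. The tables were never fitted together. There were 18 comparisons, 8 between infected groups, 8 of infected groups with naive cells and 2 interaction terms, each with a quasi-likelihood F test, two-sided, and Benjamini-Hochberg adjustment over the genes of that comparison. A gene was called at an adjusted p under 0.05. The 22 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 396 list tests 191 were called, and 91 of these calls were lost with an estimated correlation. The p printed beside a list is the one with an estimated correlation unless camera is named with it.

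The groups, comparisons, lists, alternatives and the rule for naming genes were set before the data were examined. The lists cover stem and memory, effector and cytotoxic, inhibitory and exhaustion, S-phase, G2/M, interferon-stimulated, glycolysis, respiratory chain, receptor activation, homing receptor, cytokine receptor, ribosome biogenesis, and stress and immediate-early genes, and markers of B cells, plasma cells, CD4 T cells, myeloid cells, neutrophils, NK cells, erythroid cells, platelets and dendritic cells; some genes stand in more than 1 list. Genes named for a comparison are among the 10 largest changes per direction with a mean of at least 10 CPM and no overlap of the libraries, up to 4 members of a list with the smallest p, members needed to state a list's exceptions, or a fixed set of 12 markers, among them Tcf7, Tox, Pdcd1, Gzmb, Mki67, Il7r, Slamf6, Cx3cr1, Klrg1, Id3 and Prdm1. A few genes that this rule would name are not reported here. Levels given per library for sorting markers and markers of other cells, and genes named otherwise, were chosen after their values were seen where the text says so. Fold changes against a group with 0 counts are given as lower bounds computed from 3 counts over the group. Shares of receptor segments have 95% Wilson intervals.

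Alternatives were RLE size factors, no filter beyond a total above 0, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, the library number as a block, a fit of only the groups compared, an estimated correlation for the lists, and each library left out in turn. The block was set within a day or infection for stem-like against TD cells and for the interactions. For the other comparisons it joined equal numbers across all groups. On simulated counts with known changes, the tests of the 18 comparisons called 4.48% to 34.3% of genes changed 1.5-fold, 17.9% to 52.2% at 2-fold and 40.9% to 72.7% at 4-fold, with 0% to 17.6% of calls false. The changed list was called in 18 of 18 and 1 other list was called. Simulated genes were drawn independently of each other, so the list result does not cover correlated genes. Only 200 genes were changed, fewer than most real comparisons called, so these rates need not hold for the real counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.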

Results

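The series asks how an early CD8 T cell precursor takes on its programme when a virus is cleared and when it persists. RNA was sequenced from CD8 T cells of mouse spleen, either naive or recognising GP33, a peptide of the lymphocytic choriomeningitis virus (LCMV) glycoprotein. The Armstrong strain of LCMV causes an acute infection that is cleared, and clone 13 (Cl13) causes a chronic one. The time-course experiment held 15 libraries of 5 groups with 3 libraries each. These were stem-like and TD cells at day 5.5 and at day 48 of chronic infection, and naive cells of uninfected mice. The strain experiment held 14 libraries of stem-like and TD cells from Cl13 and Armstrong (Arm) mice at day 5 and of naive cells. Each group had 3 libraries except Cl13 TD, which had 2. The labels define TD cells as Tim-3+ and, in the titles of the time-course experiment, stem-like cells as CD73+. They do not spell out TD, nor the marks GK and hi. GK stands in every day 5.5 title and in no day 48 title, and hi in every Arm title and in no Cl13 title. What these marks stand for therefore cannot be told apart from the day or the strain. The days of the time course are those of the titles, and the protocol text gives slightly different ones. A Cl13 TD library numbered 2 was not analysed here.

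Per library there were 19149046 to 27064042 counts in the time course and 23435223 to 31906086 in the strain experiment. There were 16988 to 19021 and 15957 to 17981 genes detected, in the same order. At these depths a gene with 0 counts in a library could lie at up to 0.105 to 0.157 and 0.0956 to 0.125 CPM (counts scaled to library size), for counting error alone. Levels are given as mean ± SD in CPM and log2 fold changes are ± SE, with the first group named over the second. The SE was computed as the absolute log2 fold change over the square root of its F statistic. It is approximate, above all for genes with few counts in a group. In a principal component analysis the first 2 components held 53.8% and 24.6% of the variance in the time course and 73.4% and 16.5% in the strain experiment.

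The transcripts of the sorting markers followed the labels and are a check of them, not a finding. Nt5e, which encodes CD73, stood at 129.6 ± 11, 142 ± 16.6, 108 ± 19.3 and 120 ± 24.7 CPM in the day 5.5, day 48, Cl13 and Arm stem-like groups. In the TD groups it was at 11.8 ± 2.09, 5.97 ± 3.18, 6.42 ± 5.01 and 3.28 ± 3.25 CPM. Havcr2, which encodes Tim-3, stood at 1.82 ± 1.20, 1.28 ± 0.643, 7.89 ± 0.502 and 7.97 ± 1.53 CPM in the stem-like groups. Its TD levels were 276 ± 5.51, 480.3 ± 86.8, 369 ± 16.7 and 364 ± 4.73 CPM. Cd44, a receptor that marks antigen-experienced T cells, was at 18.4 ± 1.94 and 9.90 ± 2.25 CPM in the naive groups and between 117 and 166 CPM in the infected groups. Pdcd1, which encodes PD-1, was at 2.51 ± 0.910 and 1.92 ± 1.59 CPM in the naive groups.

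Some libraries also held transcripts of other cell types, shown here by genes chosen after their values were seen. The first day 48 stem-like and first day 48 TD libraries had the B cell genes Cd79a at 32.1 and 27.7 CPM and Ms4a1 at 26.3 and 30.8 CPM. Cd79a was at 0.575 to 1.97 CPM in the 4 other day 48 libraries. Cd74, an antigen presentation gene, was at 255.5 and 320.3 CPM in that pair and at 46.9 to 53.4 CPM in the 4 others. The first day 48 TD library also had the macrophage genes Lyz2 at 85.0 and Apoe at 37.4 CPM. Cd4 was at 3.61 to 10.7 CPM in the day 48 libraries and at no more than 3.43 CPM in those of day 5.5. In the strain experiment, the first Cl13 stem-like library had the neutrophil genes S100a8 at 48.0 and S100a9 at 82.6 CPM and the plasma cell gene Jchain at 78.7 CPM. Library 3 of the Cl13 stem-like group had S100a8 at 22.9, Lyz2 at 84.4 and Cd74 at 111.5 CPM, and library 2 had S100a8 at 1.34 and Lyz2 at 6.34 CPM. Cl13 stem-like library 1 also had 0.827% mitochondrial counts, against 0.306% to 0.447% in the other infected libraries of its experiment. On principal component 4, with 1.25% of the variance, it lay at 19.3 and its replicates at -6.86 and -5.68. Arm stem-like library 1 had S100a8 at 16.8 and S100a9 at 21.4 CPM. Plasma cell markers summed to 175 CPM in day 48 stem-like library 3 and to 9.19 and 25.3 CPM in its replicates.

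The first comparison asks how stem-like and TD cells differed early in chronic infection, at day 5.5 (n = 3 libraries in each group). Tcf7, which encodes the transcription factor TCF-1 of stem-like T cells, was at 2074 ± 116 CPM in stem-like and 52.9 ± 4.58 CPM in TD cells, a log2 fold change of 5.29 ± 0.20 (adjusted p = 2.7e-10). Gzmb, the cytotoxic protease granzyme B, went the other way, at 39.5 ± 2.77 against 4253 ± 167 CPM (log2 fold change -6.75 ± 0.23, adjusted p = 1.5e-10). Among the largest increases in stem-like cells were the chemokine receptors Ccr6 (7.46 ± 0.85), Cxcr5 (6.58 ± 0.21) and Ccr7 (5.71 ± 0.35), the ATP-gated channel P2rx7 (6.64 ± 0.41) and the transcription regulator Id3 (5.63 ± 0.21). Among the largest decreases were the ecto-nucleotidase Entpd1 (-5.66 ± 0.33), the integrin chain Itgam (-5.74 ± 0.86), granzyme A, Gzma (-5.25 ± 0.18), and Prdm1, which encodes the effector regulator Blimp-1 (-5.28 ± 0.38). Pdcd1 did not pass (log2 fold change 0.44 ± 0.16, adjusted p = 0.0581), at 627 ± 23.2 against 462 ± 21.8 CPM. It was called by DESeq2 (0.41), with the stricter filter (0.46), with the library number as a block (0.44) and in a fit of these 6 libraries alone (0.46). Tcf7 is gene ENSMUSG00000000782 on chromosome 11, from 52252371 to 52283014. Gzmb is ENSMUSG00000015437 on chromosome 14, from 56258838 to 56262260. Both are protein-coding genes on the minus strand of the mm10 (GRCm38) build, and their counts are over whole genes.

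At day 5.5 the stem and memory, effector, S-phase and interferon-stimulated lists held their calls. Of the stem and memory list, 26 of 30 tested members were higher, 0 lower and 4 did not pass (27 and 0 adjusted over the list alone), among them Tnfsf8 (4.91 ± 0.16). The median log2 fold change was 2.02 (adjusted p = 1.7e-06 with an estimated correlation). In the effector and cytotoxic list, 2 of 34 tested members were higher, 26 lower and 6 did not pass (2 and 28 adjusted over the list alone). Fasl, a death ligand, was at -4.16 ± 0.17 and perforin, Prf1, at -2.74 ± 0.09. Gzmm and Ctsw were the exceptions that rose (adjusted p = 1.4e-04 with an estimated correlation). DNA replication genes of the S-phase list were lower throughout, in that 0 of 33 tested members were higher, 33 lower and 0 did not pass (the same counts adjusted over the list alone). Among them were Mcm4 (-1.12 ± 0.08) and Pold1 (-1.35 ± 0.10; adjusted p = 0.0117 with an estimated correlation). In the G2/M list 0 of 34 tested members were higher, 31 lower and 3 did not pass (0 and 34 adjusted over the list alone), including Cdk1 (-1.57 ± 0.16) and Mki67 (-1.50 ± 0.17). This list's call was lost (adjusted p = 0.0807 with an estimated correlation). Interferon-stimulated genes were higher in stem-like cells, where 39 of 42 tested members were higher, 0 lower and 3 did not pass (the same counts adjusted over the list alone). Ifit1 was at 2.92 ± 0.10 and Ddx60 at 2.81 ± 0.13 (adjusted p = 4.8e-07 with an estimated correlation). The inhibitory and exhaustion list went both ways and was not called (camera adjusted p = 0.59). Of it, 9 of 30 tested members were higher, 9 lower and 12 did not pass (10 and 11 adjusted over the list alone). Tox (0.98 ± 0.08) and Ikzf2 (2.24 ± 0.18) were higher and Cxcr6 (-2.85 ± 0.11) lower.

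Glycolysis genes at day 5.5 counted 0 of 18 higher and 13 lower (the same adjusted over the list alone), with the glucose transporter Slc2a3 at -1.12 ± 0.10. Respiratory chain genes counted 2 of 52 higher and 13 lower (2 and 15 adjusted over the list alone), with cytochrome c, Cycs, at -0.66 ± 0.10. Neither call held, at adjusted p = 0.0946 and 0.616 with an estimated correlation. Receptor activation genes (9 of 30 higher and 7 lower, 11 and 9 adjusted over the list alone) included the adhesion receptor Crtam at 2.86 ± 0.19 and Il2ra, the high-affinity IL-2 receptor chain, at -4.49 ± 0.41. Homing receptors (6 of 23 higher and 11 lower, 7 and 11 adjusted over the list alone) included Itgb1 at 1.58 ± 0.11. Cytokine receptors (8 of 27 higher and 6 lower, 9 and 6 adjusted over the list alone) included Il6ra at 3.68 ± 0.29. Ribosome biogenesis (4 of 27 higher and 2 lower, 4 and 3 adjusted over the list alone) and stress and immediate-early genes (2 of 23 higher and 8 lower, 4 and 9 adjusted over the list alone) included Npm1 at 0.40 ± 0.08 and Dusp1 at -1.81 ± 0.22. None of these 5 lists was called as a set.

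NK markers, which effector CD8 T cells share in part, counted at day 5.5 0 of 9 higher and 4 lower (1 and 5 adjusted over the list alone), including Klra7 (-3.65 ± 0.57) and Fcer1g (-4.62 ± 0.40). Their call was lost (adjusted p = 0.0669 with an estimated correlation). B cell markers counted 3 of 17 higher and 0 lower (the same adjusted over the list alone), with Ighm at 1.36 ± 0.18 and Cd22, an inhibitory sialic acid receptor, at 3.23 ± 0.58. Myeloid markers counted 1 of 19 higher and 3 lower (the same adjusted over the list alone) and dendritic cell markers 1 of 7 higher and 3 lower (2 and 3 adjusted over the list alone), with Hmox1 at -1.29 ± 0.21 and Xcr1 at -2.45 ± 0.43. Of CD4 T cell markers 0 of 6 were higher and 1 lower, and of neutrophil markers 0 of 3 and 1. Plasma cell, erythroid and platelet markers had 0 of 5, 0 of 6 and 0 of 3 changed. The counts of these 5 lists were the same adjusted over the list alone. Across all genes, edgeR called 3644 of 15544 tested genes, 1677 higher and 1967 lower in stem-like cells, of which 1365 changed at least 2-fold. In 44.5% of the tested genes the libraries of the groups did not overlap, where chance gives 10% for 3 against 3.

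**Figure D1:**
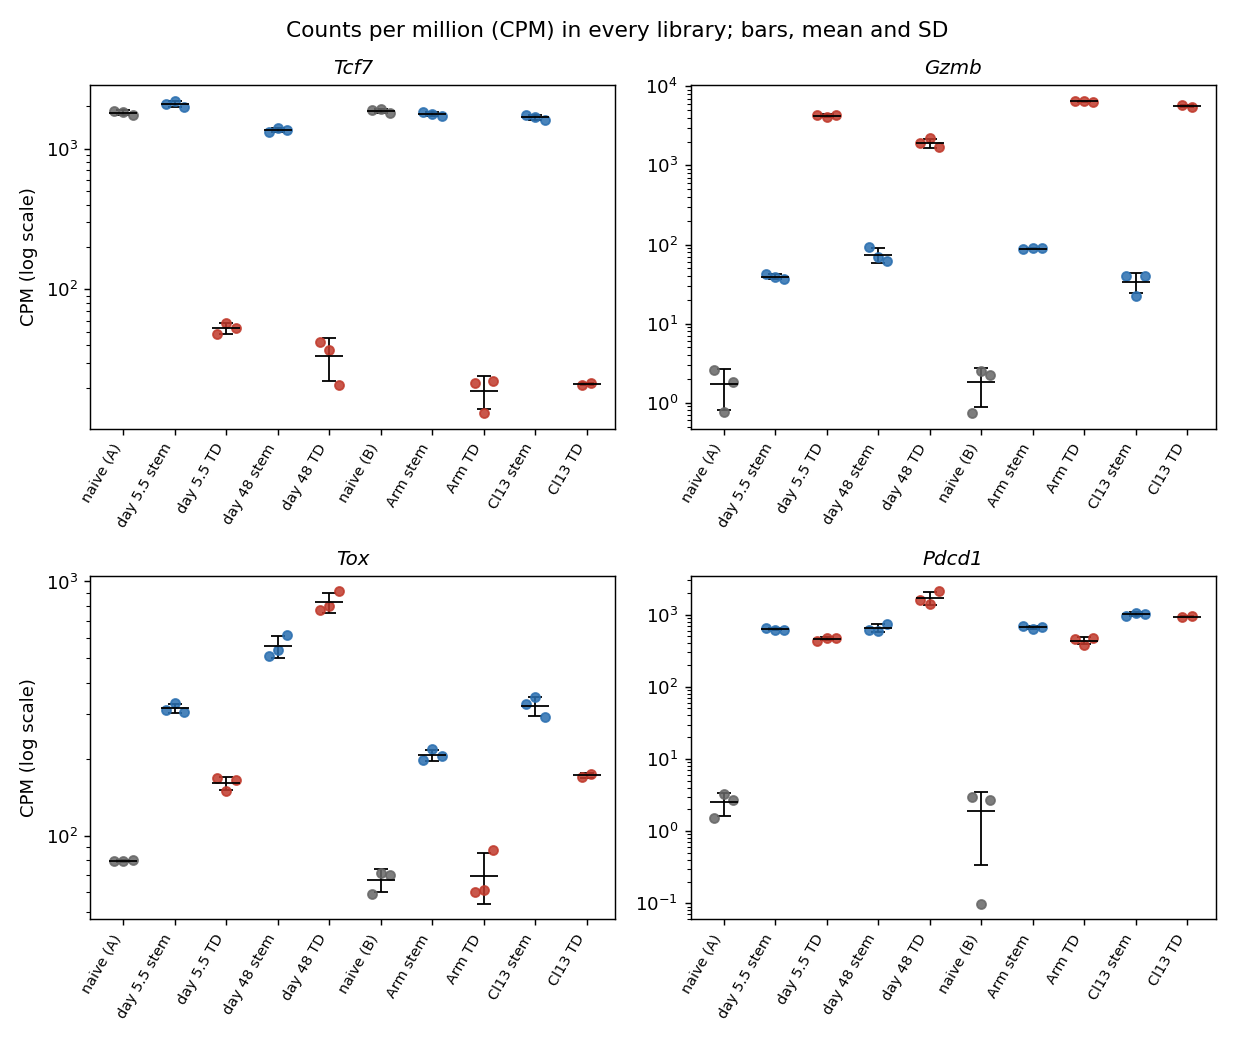
CPM (log scale) of Tcf7, Gzmb, Tox and Pdcd1 in each library of the 10 groups, with bars for the mean and SD. Tcf7 lay near 2074 CPM in day 5.5 stem-like and 52.9 CPM in day 5.5 TD libraries, and Gzmb at 39.5 and 4253 CPM.

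At day 48 the comparison of stem-like with TD cells asks the same question once infection had become chronic (n = 3 each). Tcf7 stood at 1357 ± 42.7 against 33.6 ± 11.2 CPM (5.33 ± 0.20). The memory genes Slamf6 (3.85 ± 0.11), Id3 (7.34 ± 0.23) and Il7r (3.24 ± 0.31) were higher in stem-like cells. Pdcd1, at 655 ± 81.5 against 1709 ± 356 CPM, was lower in stem-like cells (-1.38 ± 0.16), as were Tox (-0.58 ± 0.08), Gzmb (-4.69 ± 0.21) and the fractalkine receptor gene Cx3cr1 (-2.72 ± 0.44). Against TD groups with 0 counts, Sostdc1, a secreted signalling antagonist, was at least 967-fold higher in stem-like cells and the chemoattractant receptor Gpr15 at least 307-fold. The collagen receptor Mrc2, with 0 counts in stem-like cells, was at least 1620-fold lower there, and Rasd2 at least 881-fold.

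In the stem and memory list at day 48 26 of 30 tested members were higher, 0 lower and 4 did not pass (the same counts adjusted over the list alone). This call held (adjusted p = 3.6e-06 with an estimated correlation). Among effector and cytotoxic genes 3 of 34 tested members were higher, 27 lower and 4 did not pass (3 and 28 adjusted over the list alone), with Gzma at -5.87 ± 0.18 and the chemokine Ccl3 at -5.05 ± 0.19. Gzmm, Tnf and Ctsw were higher (adjusted p = 1.8e-04 with an estimated correlation), Gzmm not passing in a fit of these 6 libraries alone (1.21). Of the inhibitory and exhaustion list, 3 of 30 tested members were higher, 23 lower and 4 did not pass (4 and 23 adjusted over the list alone), including Entpd1 (-5.55 ± 0.30) and Cd7 (-2.54 ± 0.13). Batf, Ikzf2 and Btla rose (adjusted p = 0.00466 with an estimated correlation). Batf and Ikzf2 lost their calls without stem-like library 3, at 0.24 and 0.52. Interferon-stimulated genes counted 27 of 42 higher and 3 lower (28 and 3 adjusted over the list alone), with Slfn5 at 3.81 ± 0.17 and Oasl2 at 3.75 ± 0.28 (adjusted p = 1.8e-04 with an estimated correlation). Ifi47, Parp14 and Lgals3bp were lower but lost their calls without a stem-like library, at -0.19 and -0.46 without library 1 and -0.17 without library 2. With the library number as a block Lgals3bp lost its call as well (-0.27). Ribosome biogenesis genes were higher in stem-like cells, with 19 of 27 higher and 0 lower (21 and 0 adjusted over the list alone). They included the polyamine enzyme Srm (1.13 ± 0.12) and Myc (1.01 ± 0.10; adjusted p = 0.00408 with an estimated correlation). Cell division genes were lower, with 0 of 33 higher and 26 lower (0 and 27 adjusted over the list alone) in S phase and 0 of 34 higher and 28 lower (0 and 31 adjusted over the list alone) in G2/M. NK markers counted 0 of 9 higher and 4 lower (1 and 5 adjusted over the list alone). These calls were lost (adjusted p = 0.112, 0.112 and 0.153 with an estimated correlation). Among 15544 genes edgeR called 4697, 2234 higher and 2463 lower, and a fit of these 6 libraries alone called 2762. One library of each day 48 group carried the B cell transcripts given above.

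Whether the stem-like against TD difference itself changed between the days was tested with an interaction term. A positive value means that the day 48 difference was shifted towards stem-like cells. Tcf7 showed no such shift (0.04 ± 0.24). Pdcd1 (-1.83 ± 0.22) and Tox (-1.55 ± 0.11) shifted towards TD cells, whereas Gzmb (2.06 ± 0.26), Id3 (1.71 ± 0.28) and Slamf6 (1.47 ± 0.14) shifted towards stem-like cells. Il2ra shifted by 5.68 ± 0.55, since its level was 3.03 and 68.2 CPM in day 5.5 stem-like and TD cells and 8.16 and 3.57 CPM at day 48. Inhibitory and exhaustion genes shifted towards TD cells, with 2 of 30 higher and 16 lower (2 and 17 adjusted over the list alone), among them Cd7 (-3.95 ± 0.18) and Ptger4 (-1.71 ± 0.14; adjusted p = 0.00516 with an estimated correlation). Interferon-stimulated genes did so as well, with 0 of 42 higher and 20 lower (0 and 23 adjusted over the list alone), such as Ifit1 (-1.59 ± 0.13; adjusted p = 2.3e-04 with an estimated correlation). Ribosome biogenesis genes shifted towards stem-like cells, with 12 of 27 higher and 0 lower (17 and 0 adjusted over the list alone), such as Nop56 (1.01 ± 0.12; adjusted p = 0.00412 with an estimated correlation). S-phase, homing receptor and CD4 T cell lists were called upward, but lost these calls (adjusted p = 0.545, 0.189 and 0.114 with an estimated correlation). With the library number as a block the CD4 T cell list was not called either (adjusted p = 0.0764). The interaction was called by edgeR for 2057 of 15544 genes, 924 positive and 1133 negative.

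**Figure D2:**
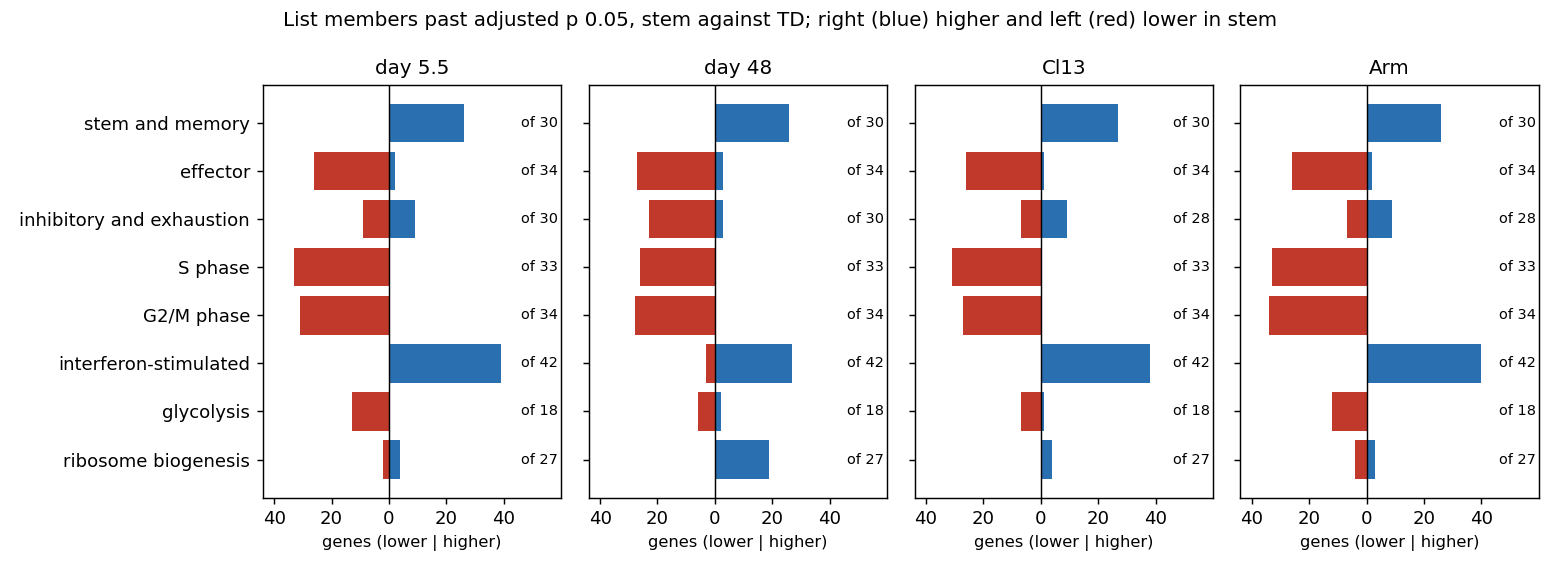
Number of members of 8 gene lists past the adjusted p threshold in stem-like against TD cells, with members higher in stem-like cells to the right and lower to the left, for day 5.5, day 48, Cl13 and Arm. In the stem and memory list 26, 26, 27 and 26 members were higher, and in the inhibitory and exhaustion list 9, 23, 7 and 7 were lower.

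Day 48 stem-like cells were next compared with day 5.5 stem-like cells, to see what changed in this population over time (n = 3 each). Penk, an opioid peptide precursor, rose from 0.907 ± 1.03 to 292 ± 45.8 CPM (8.31 ± 0.61). Spp1, which encodes osteopontin, rose by 5.68 ± 0.56. Il1rl1, the IL-33 receptor chain ST2, fell from 62.5 ± 5.15 to 1.16 ± 1.85 CPM (-5.71 ± 0.86). Il12rb2, an IL-12 receptor chain, fell as well (-3.88 ± 0.47). Ccl5, a chemokine of memory T cells, rose from 116 ± 21 to 740.1 ± 171 CPM (2.68 ± 0.17). Tox (0.81 ± 0.08) and the integrin chain Itgae (4.24 ± 0.34) rose with it. Tcf7 fell slightly, at -0.61 ± 0.16 (adjusted p = 0.00773) and Mki67, a marker of dividing cells, at -1.01 ± 0.17. Glycolysis genes fell, with 0 of 18 higher and 16 lower (the same adjusted over the list alone), such as Ldha (-1.82 ± 0.07) and Pkm (-1.58 ± 0.06; adjusted p = 5.2e-04 with an estimated correlation). Interferon-stimulated genes rose, with 26 of 42 higher and 5 lower (28 and 5 adjusted over the list alone), such as Irf7 (1.09 ± 0.09; adjusted p = 0.0036 with an estimated correlation).

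Other lists moved over time in stem-like cells but lost their call once the correlation was estimated. S-phase genes counted 0 of 33 higher and 30 lower (0 and 31 adjusted over the list alone), G2/M genes 0 of 34 higher and 32 lower (0 and 33 adjusted over the list alone) and respiratory chain genes 1 of 52 higher and 41 lower (the same adjusted over the list alone). Mcm5 was at -1.83 ± 0.14, Ccna2 at -2.78 ± 0.23 and Sdha at -0.88 ± 0.07 (adjusted p = 0.066, 0.0616 and 0.0616 with an estimated correlation). Effector (18 of 34 higher and 9 lower, 19 and 10 adjusted over the list alone), inhibitory (16 of 30 higher and 4 lower, the same adjusted over the list alone) and receptor activation genes (12 of 30 higher and 6 lower, 13 and 6 adjusted over the list alone) moved in part. They included Id2 at 1.85 ± 0.10, Cd200r1 at 2.70 ± 0.21 and Nfkbid at 1.96 ± 0.15 (adjusted p = 0.377, 0.24 and 0.219 with an estimated correlation). Myeloid markers counted 12 of 19 higher and 1 lower (the same adjusted over the list alone) and NK markers 6 of 9 higher and 0 lower (the same adjusted over the list alone), with C1qa at 4.81 ± 0.64 and Fcer1g at 4.03 ± 0.39. They lost their calls (adjusted p = 0.24 and 0.24 with an estimated correlation). The stem and memory list counted 7 of 30 higher and 11 lower (12 and 11 adjusted over the list alone) and was not called (camera adjusted p = 0.309). In total edgeR called 6354 of 15544 genes, 3146 higher and 3208 lower at day 48, 2777 of them by at least 2-fold.

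TD cells of day 48 and day 5.5 were compared in the same way (n = 3 each). Cd200r2, a receptor gene of the CD200 receptor family, had 0 counts at day 5.5 and was at least 5350-fold higher at day 48. Cd7 (4.47 ± 0.14), Cd200r1 (5.70 ± 0.25) and Tox (2.36 ± 0.08) rose. Pdcd1 rose from 462 ± 21.8 to 1709 ± 356 CPM (1.89 ± 0.16). Il1rl1, at 25.8 ± 4.06 CPM at day 5.5, had 0 counts at day 48, at least 618-fold lower. Il2ra (-4.25 ± 0.40), Gzmb (-1.14 ± 0.18) and Klrg1, a receptor of terminal effector cells (-1.96 ± 0.40), fell. In the inhibitory and exhaustion list 24 of 30 tested members were higher, 2 lower and 4 did not pass (24 and 3 adjusted over the list alone), and this call held (adjusted p = 0.00583 with an estimated correlation). Of the interferon-stimulated list 36 of 42 tested members were higher, 1 lower and 5 did not pass (37 and 1 adjusted over the list alone). Ifit3 was among those higher (3.01 ± 0.17), and the list held its call (adjusted p = 4.4e-05 with an estimated correlation). Glycolysis genes counted 1 of 18 higher and 16 lower (the same adjusted over the list alone), with Eno1 at -1.83 ± 0.08 (adjusted p = 7.3e-04 with an estimated correlation). Ribosome biogenesis genes counted 0 of 27 higher and 25 lower (the same adjusted over the list alone), with Fbl at -1.43 ± 0.08 (adjusted p = 0.00381 with an estimated correlation). S-phase genes (0 of 33 higher and 33 lower, the same adjusted over the list alone) and respiratory chain genes (0 of 52 higher and 42 lower, the same adjusted over the list alone) fell too. Mcm2 was at -1.71 ± 0.12 and Cyc1 at -1.41 ± 0.08 (adjusted p = 0.0202 and 0.0314 with an estimated correlation). G2/M genes (0 of 34 higher and 34 lower, the same adjusted over the list alone) and receptor activation genes (14 of 30 higher and 6 lower, the same adjusted over the list alone) lost their calls (adjusted p = 0.0585 and 0.0778 with an estimated correlation). The macrophage genes Apoe (4.50 ± 0.81) and Vcam1 (5.12 ± 1.12) were also higher at day 48, where the first TD library held the Lyz2 and Apoe levels given above. edgeR called 6986 of 15544 genes, 3478 higher and 3508 lower at day 48.

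In the strain experiment, stem-like and TD cells of Cl13 infection at day 5 were compared (n = 3 and 2 libraries). Tcf7 stood at 1666 ± 60.1 against 21.3 ± 0.454 CPM (6.29 ± 0.19), with Id3 (5.77 ± 0.15) and Il7r (2.25 ± 0.29) also higher in stem-like cells. Gzmb (-7.37 ± 0.27), Gzma (-6.36 ± 0.22), Prf1 (-2.99 ± 0.13) and Cx3cr1 (-3.40 ± 0.41) were lower. Cxcr5 and Ccr6 had 0 counts in TD cells and were at least 2130-fold and 1440-fold higher in stem-like cells. The receptor tyrosine kinase Kit was at least 433-fold higher. Stem and memory genes counted 27 of 30 higher and 0 lower (27 and 1 adjusted over the list alone), at adjusted p = 1.0e-06 with an estimated correlation. Effector and cytotoxic genes counted 1 of 34 higher and 26 lower (2 and 29 adjusted over the list alone), Ctsw being the exception that rose (adjusted p = 9.5e-06 with an estimated correlation). Interferon-stimulated genes counted 38 of 42 higher and 0 lower (the same adjusted over the list alone), such as Ifit3 (4.35 ± 0.30; adjusted p = 0.00875 with an estimated correlation). S-phase genes (0 of 33 higher and 31 lower, 0 and 32 adjusted over the list alone) and G2/M genes (0 of 34 higher and 27 lower, 0 and 29 adjusted over the list alone) were lower. Rrm2 was at -1.55 ± 0.09 and Kif11 at -0.90 ± 0.10 (adjusted p = 0.00276 and 0.0286 with an estimated correlation). Dendritic cell markers counted 1 of 7 higher and 3 lower (the same adjusted over the list alone), including the chemokine receptor Xcr1 (-3.44 ± 0.45). NK markers counted 1 of 7 higher and 2 lower (the same adjusted over the list alone), and both lists were called lower (adjusted p = 0.0459 and 0.0286 with an estimated correlation). The inhibitory and exhaustion list was not called, with 9 of 28 higher and 7 lower (10 and 8 adjusted over the list alone). Btla (1.68 ± 0.15) was higher and Cxcr6 (-3.85 ± 0.15) lower. B cell markers (5 of 15 higher and 0 lower, 6 and 1 adjusted over the list alone), receptor activation genes (10 of 30 higher and 4 lower, 11 and 6 adjusted over the list alone) and glycolysis genes (1 of 18 higher and 7 lower, 2 and 9 adjusted over the list alone) lost their calls. They were at adjusted p = 0.328, 0.19 and 0.328 with an estimated correlation. edgeR called 3270 of 15507 genes, 1645 higher and 1625 lower. Leaving out Cl13 TD library 1 gave 2106 and library 3 gave 2160. Without stem-like libraries 1 and 3 the count was 1758, an alternative chosen after seeing the data. It leaves 1 stem-like library, whose spread is taken from the other groups.

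Stem-like and TD cells of acute Armstrong infection at day 5 were compared (n = 3 each). Tcf7 was at 1761 ± 56.6 against 19.1 ± 5.04 CPM (6.53 ± 0.16), Id3 at 6.62 ± 0.13 and the interleukin receptor Il7r at 2.99 ± 0.26. Gzmb (-6.18 ± 0.25), Gzma (-6.25 ± 0.21), Prdm1 (-4.07 ± 0.39) and S1pr5, a receptor for egress (-6.66 ± 1.06), were lower in stem-like cells. Tox was higher (1.57 ± 0.13). Stem and memory genes counted 26 of 30 higher and 0 lower (27 and 0 adjusted over the list alone). Effector and cytotoxic genes counted 2 of 34 higher and 26 lower (2 and 27 adjusted over the list alone), with Ctsw and Klrk1 the exceptions. Interferon-stimulated genes counted 40 of 42 higher and 0 lower (the same adjusted over the list alone), with Irf7 at 2.09 ± 0.12. All 3 lists held their calls (adjusted p = 1.5e-06, 1.2e-04 and 0.00359 with an estimated correlation). S-phase genes counted 0 of 33 higher and 33 lower (the same adjusted over the list alone) and G2/M genes 0 of 34 higher and 34 lower (the same adjusted over the list alone), with Rrm1 at -1.36 ± 0.09 and Aurkb at -1.53 ± 0.13. These calls held (adjusted p = 5.1e-04 and 0.00375 with an estimated correlation). Cytokine receptor genes (11 of 27 higher and 5 lower, 12 and 6 adjusted over the list alone), including Il6st (2.08 ± 0.15), and glycolysis genes (0 of 18 higher and 12 lower, 0 and 13 adjusted over the list alone) lost their calls (adjusted p = 0.2 and 0.154 with an estimated correlation). NK markers (0 of 7 higher and 2 lower, the same adjusted over the list alone) held theirs, at adjusted p = 0.0183 with an estimated correlation. The inhibitory and exhaustion list counted 9 of 28 higher and 7 lower (9 and 8 adjusted over the list alone) and was not called. edgeR called 4424 of 15507 genes, 2321 higher and 2103 lower in stem-like cells.

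Stem-like cells of Cl13 and Armstrong infection at day 5 were compared to ask how early the chronic infection marks this population (n = 3 each). Ccl5 was lower in Cl13, at 28.0 ± 6.48 against 201 ± 35.2 CPM (-2.85 ± 0.16, adjusted p = 2.3e-06). So were the interferon-induced GTPase Gbp8 (-1.73 ± 0.16), the cyclin Ccnd2 (-1.44 ± 0.09) and Gzmb (-1.38 ± 0.21). Cirbp, a cold-inducible RNA-binding protein, was higher, at 76.5 ± 19.3 against 18.3 ± 0.811 CPM (2.07 ± 0.17, adjusted p = 8.2e-05). So were Il1rl1 (1.69 ± 0.20), Gldc (1.77 ± 0.22) and Nr4a2 (1.60 ± 0.18), a nuclear receptor induced by receptor signalling. Pdcd1, at 1019 ± 51.7 against 671 ± 35.3 CPM (0.60 ± 0.28), and Tcf7 (-0.08 ± 0.12) did not pass. A fit of these 6 libraries alone called Pdcd1 (0.59). Its libraries lay at 962 to 1063 CPM in Cl13 and 634 to 704 CPM in Arm, so the missing call does not show equal levels. Receptor activation genes were higher in Cl13, with 9 of 30 higher and 0 lower (14 and 0 adjusted over the list alone), such as Egr2 (1.46 ± 0.25) and Irf4 (1.19 ± 0.21; adjusted p = 0.00691 with an estimated correlation). G2/M genes (19 of 34 higher and 0 lower, 27 and 0 adjusted over the list alone), S-phase genes (9 of 33 higher and 0 lower, 16 and 0 adjusted over the list alone) and inhibitory genes (6 of 28 higher and 2 lower, 10 and 3 adjusted over the list alone) were higher too. Ccnb2 was at 0.82 ± 0.12, Rrm1 at 0.72 ± 0.09 and Btla at 0.74 ± 0.13 (adjusted p = 0.0118, 0.0279 and 0.018 with an estimated correlation). Effector (2 of 34 higher and 10 lower, 5 and 12 adjusted over the list alone), homing receptor (1 of 23 higher and 7 lower, 1 and 12 adjusted over the list alone) and stress genes (0 of 24 higher and 5 lower, 1 and 11 adjusted over the list alone) were lower. Klrd1 was at -0.73 ± 0.13, Selplg at -0.49 ± 0.07 and the chaperone Hspa8 at -0.69 ± 0.08 (adjusted p = 0.018, 0.0332 and 0.018 with an estimated correlation). Ribosome biogenesis genes counted 3 of 27 higher and 0 lower (18 and 0 adjusted over the list alone), with Ncl at 0.43 ± 0.07 (adjusted p = 0.0322 with an estimated correlation). Dendritic cell markers counted 0 of 7 higher and 2 lower (0 and 4 adjusted over the list alone), at adjusted p = 0.0208 with an estimated correlation. Stem and memory genes (1 of 30 higher and 6 lower, the same adjusted over the list alone), including Ltb (-0.82 ± 0.07), and interferon-stimulated genes (0 of 42 higher and 8 lower, 0 and 11 adjusted over the list alone) lost their calls. They were at adjusted p = 0.0715 and 0.143 with an estimated correlation.

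In that comparison edgeR called 691 of 15507 genes, 330 higher and 361 lower in Cl13 stem-like cells, of which 62 changed at least 2-fold. DESeq2 called 1342, and leaving out 1 library gave from 294 (without Arm library 2) to 621. The counts were 315 without Arm library 1, 378 without Cl13 library 3 and 396 without Cl13 library 2. Leaving out Cl13 library 1 gave 527. Neutrophil markers summed to 206, 9.40 and 97.0 CPM in the Cl13 and 67.1, 0.0966 and 0.451 CPM in the Arm libraries. Without Cl13 libraries 1 and 3, an alternative chosen after seeing the data, 131 genes passed. It leaves 1 Cl13 library, whose spread is taken from the other groups, and does not tell a loss of replicates from an effect of foreign RNA. Il1rl1 (1.44), Egr2 (1.56), Irf4 (1.36), Btla (0.80), Ccnb2 (0.75) and Ncl (0.37) then did not pass. Cirbp is gene ENSMUSG00000045193 on chromosome 10, from 80165985 to 80172786 in mm10.

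**Figure D3:**
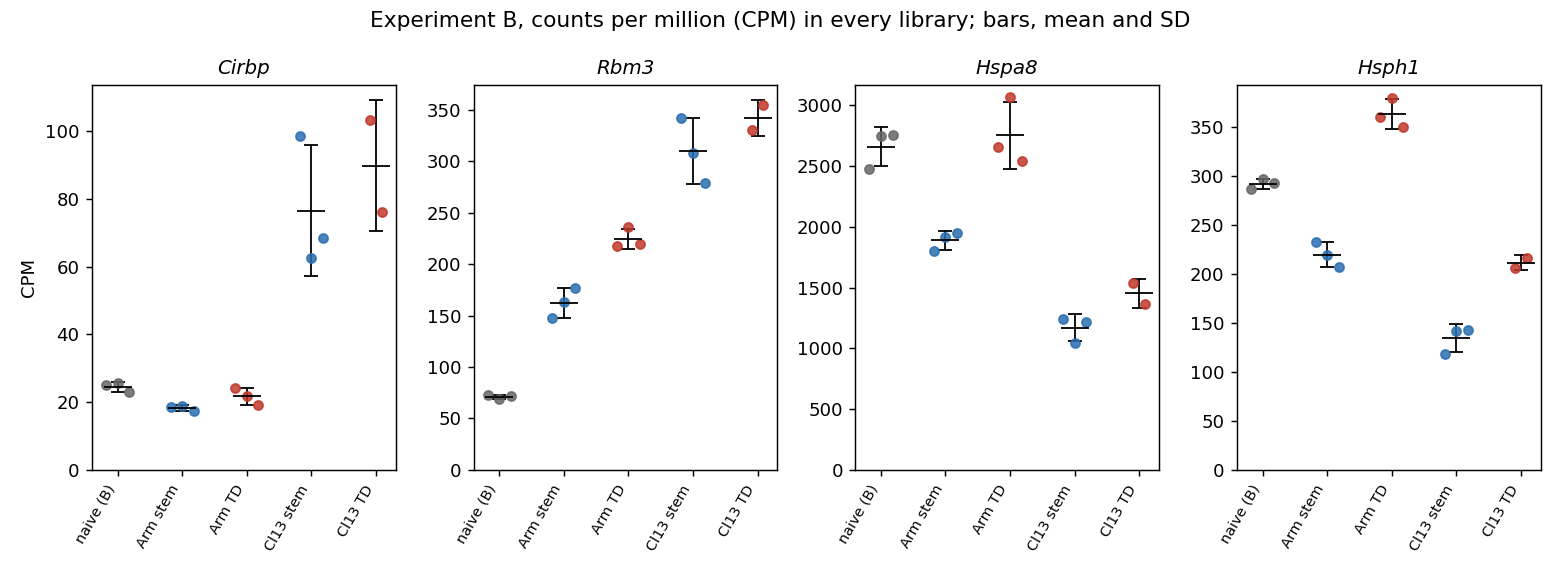
CPM of Cirbp, Rbm3, Hspa8 and Hsph1 in each library of the strain experiment, with bars for the mean and SD. Rbm3 was chosen after its values were seen. Cirbp averaged 76.5 and 89.8 CPM in Cl13 stem-like and TD libraries, 18.3 and 21.7 CPM in Arm libraries and 24.5 CPM in naive libraries.

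Between TD cells of Cl13 and Armstrong infection (n = 2 and 3 libraries), the exhaustion regulator Tox was higher in Cl13, at 173 ± 3.88 against 69.7 ± 15.6 CPM (1.31 ± 0.14). Cirbp was higher too (2.05 ± 0.19). Ltb, a lymphotoxin chain, was lower, at 59.9 ± 3.15 against 173 ± 2.94 CPM (-1.53 ± 0.08). Eomes (-1.06 ± 0.12), Cd7 (-1.35 ± 0.16) and the ADP-ribosyltransferase Art2b (-1.89 ± 0.14) were also lower. The chaperone genes Hspa8 (-0.92 ± 0.10), Hsph1 (-0.78 ± 0.09) and Dnaja1 (-0.67 ± 0.09) were lower in Cl13. Klrg1 was at 25.8 ± 3.38 against 147 ± 32.2 CPM (-2.51 ± 0.41). It passed in the full set but not without either Cl13 TD library, at -2.65 without library 1 and -2.38 without library 3. Pdcd1, at 936 ± 23.9 against 437 ± 46.7 CPM (1.10 ± 0.31), Tcf7 (0.16 ± 0.15) and Gzmb (-0.19 ± 0.22) did not pass. A fit of these 5 libraries alone called Pdcd1 (1.10). Its libraries lay at 919 to 953 CPM in Cl13 and 384 to 469 CPM in Arm, so the missing call does not show equal levels. The main fit shares its estimate of the spread with naive libraries, at 0.0987 to 2.98 CPM. Whether these widened the SE was not tested. Receptor activation genes counted 3 of 30 higher and 0 lower (5 and 1 adjusted over the list alone), stress genes 0 of 24 higher and 3 lower (0 and 6 adjusted over the list alone) and homing receptors 0 of 23 higher and 2 lower (1 and 4 adjusted over the list alone). Ribosome biogenesis genes counted 1 of 27 higher and 0 lower (the same adjusted over the list alone) and G2/M genes 0 of 34 higher and 0 lower (1 and 0 adjusted over the list alone). With an estimated correlation none of the 22 lists was called by camera, these being at adjusted p = 0.179, 0.0818, 0.35, 0.385 and 0.59. edgeR called 183 of 15507 genes, 77 higher and 106 lower, and DESeq2 676. Without Cl13 TD library 1 58 genes passed, without Cl13 TD library 3 86 and without Arm TD library 2 106. A fit of these 5 libraries alone called 119.

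Whether the stem-like against TD difference itself depended on the virus strain was tested with an interaction term in edgeR. It called 8 of 15507 genes, with 1158 at an unadjusted p under 0.05, and DESeq2 called 83. On simulated counts this test had the largest share of false calls, 12 of 68 (17.6%). Ccl5 (-1.72 ± 0.22), the cyclin Ccnd2 (-0.86 ± 0.13), the interleukin-10 receptor chain Il10ra (-0.98 ± 0.15), Nrp1 (-1.06 ± 0.15) and Pik3ip1 (-1.22 ± 0.18) were shifted towards TD cells in Cl13 relative to Arm. Ltb (0.71 ± 0.10), the chaperone Hspa5 (0.40 ± 0.06) and Cnnm3 (1.51 ± 0.24) were shifted towards stem-like cells. Of these genes, the names other than Ccl5 and Ltb were chosen after their values were seen. Leaving out 1 library gave 0 to 8 genes. The count was 0, and each of these genes lost its call, without Cl13 stem-like library 3, Cl13 TD library 3, Arm stem-like library 1 or 2, or Arm TD library 2, and with the library number as a block. The fold changes moved little, Ccl5 being at -1.78 and Ltb at 0.73 without Cl13 stem-like library 3. Camera called 11 of the 22 lists with the preset correlation and 0 with an estimated one.

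Each infected group was compared with the naive cells of its own experiment, which act as the background. In the strain experiment Trbv13-3 and Trav14-1 led the receptor counts of the infected libraries but took small shares in the naive ones, as given below. There a change against naive cells cannot be told apart from a difference in receptor or source of the cells. Tcf7 did not pass in edgeR in stem-like cells, at 0.20 ± 0.16 for day 5.5, -0.41 ± 0.16 for day 48, -0.15 ± 0.12 for Cl13 and -0.07 ± 0.12 for Arm. DESeq2 called it at day 48 (-0.39), and fits of only the groups compared called it at day 5.5 (0.23), at day 48 (-0.43) and in Cl13 (-0.16). It was lower in TD cells, at -5.09 ± 0.19, -5.74 ± 0.20, -6.44 ± 0.19 and -6.60 ± 0.16 for day 5.5, day 48, Cl13 and Arm. Pdcd1 was higher in every infected group, from 7.53 ± 0.23 in day 5.5 TD to 9.42 ± 0.24 in day 48 TD cells. Tox2, with 0 counts in the naive cells of the time course, was at least 2470-fold higher in day 5.5 stem-like, 1670-fold in day 48 stem-like and 6000-fold in day 48 TD cells. The kinesin Kif4, with 0 counts in the naive cells of the strain experiment, was at least 3180-fold higher in Cl13 stem-like, 4640-fold in Cl13 TD, 1780-fold in Arm stem-like and 4060-fold in Arm TD cells. The DNA polymerase Dntt of lymphocyte development, present in naive cells, had 0 counts in all 4 stem-like groups. It was at least 306-fold lower at day 5.5, 322-fold at day 48, 454-fold in Cl13 and 460-fold in Arm.

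Stem and memory genes were lower in the TD groups than in naive cells, with 23 of 30 members lower at day 5.5 (23 adjusted over the list alone), 21 at day 48 (22), 23 in Cl13 (23) and 23 in Arm (23). These calls held with an estimated correlation. In Cl13 stem-like cells the list was called lower, with 11 of 30 higher and 15 lower (12 and 15 adjusted over the list alone), and lost its call (adjusted p = 0.143 with an estimated correlation). Effector, inhibitory and G2/M lists were called higher in all 8 infected groups and held with an estimated correlation. In day 48 stem-like cells, effector genes counted 30 of 34 higher and 0 lower (the same adjusted over the list alone), inhibitory genes 24 of 30 higher and 1 lower (26 and 1 adjusted over the list alone) and G2/M genes 32 of 34 higher and 1 lower (the same adjusted over the list alone). Glycolysis genes were called higher at day 5.5 and in the strain experiment, with 16 of 18 higher and 0 lower (the same adjusted over the list alone) in day 5.5 TD cells, and held with an estimated correlation. They were not called at day 48. Ribosome biogenesis genes were lower at day 48, with 1 of 27 higher and 21 lower (2 and 23 adjusted over the list alone) in stem-like and 0 of 27 higher and 26 lower (1 and 26 adjusted over the list alone) in TD cells. Both calls held (adjusted p = 0.00259 and 3.0e-04 with an estimated correlation). Interferon-stimulated genes were higher at day 48 in both, with 37 of 42 higher and 1 lower (39 and 1 adjusted over the list alone) and 29 of 42 higher and 4 lower (32 and 4 adjusted over the list alone). They were at adjusted p = 1.2e-05 and 0.00208 with an estimated correlation. edgeR called 6642, 8184, 5637 and 6733 genes in the time course (day 5.5 stem-like and TD, day 48 stem-like and TD). It called 7026, 7521, 6132 and 8004 in the strain experiment (Cl13 stem-like and TD, Arm stem-like and TD). These comparisons share the naive libraries and were not set against each other.

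Fold changes of comparisons with no library in common were then correlated across genes, which are not independent replicates. Comparisons from the same table share a fit, and the labels do not say whether their libraries share mice. The counts expected by chance assume an independence that was not shown. Stem-like against TD fold changes in Cl13 and Arm had Pearson r 0.46 and Spearman rho 0.60. Of 2696 genes called in both, 2693 had the same direction. Day 5.5 and Cl13, from separate experiments, had r 0.48 and rho 0.62 over 14275 genes, with 2325 of 2326 shared calls in the same direction. Day 5.5 and day 48 had r 0.39 and rho 0.40. Here 1821 of 2033 shared calls had the same direction, 805 higher (241 expected by chance) and 1016 lower (312 expected). The change from day 5.5 to day 48 in stem-like and in TD cells had r 0.47 and rho 0.60. There 4217 of 4414 shared calls had the same direction. Cl13 against Arm in stem-like and in TD cells had r 0.05 and rho 0.25, while 99 of 100 shared calls had the same direction, 40 higher (1.64 expected) and 59 lower (2.47 expected). The shared calls were 29 without Cl13 TD library 1, 39 without Cl13 TD library 3, 63 without Arm TD library 1, 58 without Arm TD library 2 and 298 with DESeq2. Without 1 library 10 to 35 were higher.

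Ribosomal protein genes and receptor segments were summarised as families. Of 84 ribosomal protein genes, 74 were higher in day 48 stem-like than TD cells (median log2 fold change 0.71), 28 were higher and 1 lower at day 5.5 (0.27). The interaction of day and population was positive for 33. From day 5.5 to day 48, 57 fell and 3 rose in TD cells (median -0.54) and 25 fell and 13 rose in stem-like cells (-0.07). These directions were the same with size factors of the RLE type.

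In the strain experiment a single V segment of each T cell receptor chain led the counts of all 11 infected libraries. Trbv13-3 took 56.6% (95% Wilson interval 54.7 to 58.5) to 78.1% (76.2 to 80.0) of Trbv counts there and 6.35% to 6.97% in the naive libraries. Trav14-1 took 79.2% (78.2 to 80.1) to 90.6% (89.8 to 91.3) of Trav counts in infected and 3.14% to 3.50% in naive libraries. Total Trbv counts were 1383 to 2823 in the infected libraries and 14058 to 20532 in the naive ones. In the time course no Trbv segment took more than 17.4% of the Trbv counts of a library.

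**Figure D4:**
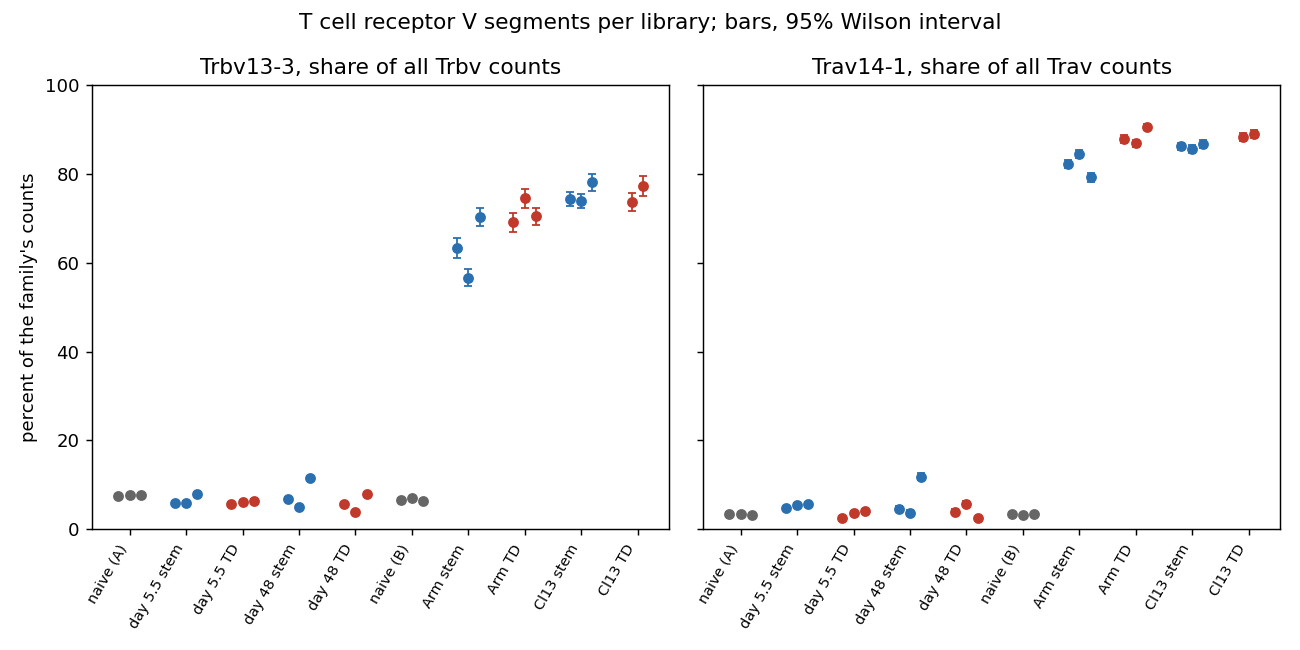
Percent of all Trbv counts on Trbv13-3 and of all Trav counts on Trav14-1 in each library, with bars for the 95% Wilson interval. Trbv13-3 lies at 56.6% or above in the infected libraries of the strain experiment and at 11.6% or below in those of the time course.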

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

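The interaction terms in this part were planned, and the counts over other splits of the libraries were chosen only after the result was seen. The stem-like against TD difference changed between day 5.5 and day 48 by the interaction test for 2057 genes and 6 gene lists. The inhibitory and exhaustion list (camera adjusted p = 1.24e-23), the interferon-stimulated list (1.84e-16) and the ribosome biogenesis list (2.74e-11) kept their calls with an estimated correlation. Genes with a called interaction of day and population were Pdcd1 (-1.83), Tox (-1.55), Cd7 (-3.95), Ptger4 (-1.71) and Ifit1 (-1.59), shifted towards TD cells. Gzmb (2.06), Id3 (1.71), Slamf6 (1.47), Il2ra (5.68) and Nop56 (1.01) shifted towards stem-like cells. Between Cl13 and Arm the interaction was called by edgeR for 8 genes and by camera for 11 lists, none of which kept its call with an estimated correlation. The genes were Ccl5 (-1.72), Pik3ip1 (-1.22), Nrp1 (-1.06), Il10ra (-0.98), Ccnd2 (-0.86), Cnnm3 (1.51), Ltb (0.71) and Hspa5 (0.40). Each lost its call when Cl13 TD library 3 was left out, since 0 genes then passed in edgeR, with Ccl5 at -1.66 and Ltb at 0.77.

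Of 100 splits of the day labels within each population, drawn at random apart from the real one, 8 gave at least as many interaction genes as the real count of 2057, the real one included. This count neither excludes chance nor argues for it, for the reasons given next. The other 7 kept the day of unequal numbers of stem-like and TD libraries, which leaves the change over time common to both populations in the interaction. The highest, 8543 genes, kept all 6 stem-like libraries and 0 TD libraries and points to that structure of the samples. The 40 other splits that kept equal numbers gave at most 0 genes. They mix libraries of both days within a group, so the change over time widens the spread and few calls follow from the construction. For 13 comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05, the real split being in each the 1 as large as itself. The other splits mix the groups compared, so their low counts follow from the construction as well. For stem-like against TD cells the real and highest other counts were 3644 and 0 at day 5.5, 4697 and 3 at day 48, and 4424 and 0 in Arm. They were 6354 and 1 for day 48 against day 5.5 stem-like cells, 6986 and 0 for TD cells, and 691 and 0 for Cl13 against Arm stem-like cells. Against naive cells they were 6642 and 1, 8184 and 0, 5637 and 2, and 6733 and 1 in the time course, in the order day 5.5 stem-like and TD, day 48 stem-like and TD. In the strain experiment they were 7026 and 1, 6132 and 0, and 8004 and 2 for Cl13 stem-like, Arm stem-like and Arm TD.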

How the results depend on the processing

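The fits without Cl13 stem-like libraries 1 and 3, and without both day 48 libraries numbered 1, were chosen only after the result was seen. Counts of genes called in a comparison stayed within 1.5 times under every alternative run except those given here. DESeq2 called 1342 genes for Cl13 against Arm stem-like cells, 676 for TD cells and 83 for the interaction of strain and population. For that interaction RLE size factors gave 5, the stricter filter 13 and a fit of only the groups compared 3. A fit of only the groups compared gave 2762 at day 48 and 119 for Cl13 against Arm TD cells. With the library number as a block, Cl13 against Arm TD gave 76 genes and the interaction of strain and population 0. For Cl13 against Arm TD the block joined libraries of different infections, whose expression deviations had r -0.04 and -0.01 for the same number. The 76 genes therefore do not reflect a known pairing of samples. In the time course, where V segment shares go with the number, the block gave 3575 genes at day 5.5, 4544 at day 48 and 1936 for the interaction of day and population. Gene lists with this block, chosen after the data were seen, were 8, 9 and 5, against 8, 8 and 6 without it. The neutrophil list at day 48 was gained (adjusted p = 0.0496) and the CD4 T cell list of the interaction lost (0.0764), and 0 of the calls with an estimated correlation changed. Without 1 library, counts ranged from 2106 to 2841 for Cl13 stem-like against TD, 294 to 621 for Cl13 against Arm stem-like, 58 to 135 for Cl13 against Arm TD and 0 to 8 for the strain interaction. Without Cl13 stem-like libraries 1 and 3 the counts were 1758, 131 and 2 for Cl13 stem-like against TD, Cl13 against Arm stem-like and the strain interaction. Where a fit leaves 1 Cl13 stem-like or 1 Cl13 TD library, its spread is taken from the other groups, so fewer calls do not show an effect of the libraries left out. The cause was not tested. Of 213 values of named genes 23 lost their call under at least 1 alternative. Among values called in the main fit or in the alternative, 0 changed direction. Changes of sign in values called in neither were not counted. In 10 values an alternative called Pdcd1 or Tcf7 where edgeR with all groups did not.

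With an estimated correlation the number of lists called fell to 4 at day 5.5, 5 at day 48 and 2 for day 48 against day 5.5 stem-like cells. It was 7 and 6 for Cl13 stem-like against TD and against naive cells. There were 9 left for Cl13 against Arm stem-like cells, 0 for TD cells, 3 and 0 for the interactions of day and of strain, 7 for day 5.5 TD against naive, and 6 each for Cl13 TD, Arm stem-like and Arm TD against naive cells. Correlations of fold changes moved with the filter. Without it r was 0.19 for day 5.5 and day 48, 0.28 for Cl13 and Arm, 0.24 for day 5.5 and Cl13, and 0.28 for the change over time in both populations. With the stricter filter these were 0.59, 0.76, 0.82 and 0.65, and 0.14 for Cl13 against Arm in both populations. Without 1 library r for Cl13 and Arm was 0.40 to 0.47. Calls shared by Cl13 against Arm in both populations ranged from 29 to 88 without 1 library and were 298 with DESeq2, against 100. Depth limits the genes near the floor, and 2 or 3 libraries per group limit the smaller changes.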

Other observations

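The tests of the 2 patterns in this part were chosen only after the result was seen, as were the genes named in it. Il1rl1, the ST2 chain of the IL-33 receptor, was present early and scarce late in both populations. It was at 62.5 ± 5.15 and 25.8 ± 4.06 CPM in day 5.5 stem-like and TD cells, 1.16 ± 1.85 CPM in day 48 stem-like cells and with 0 counts in day 48 TD cells. It averaged 0.0234 ± 0.0405 CPM in the naive libraries of the time course and had 0 counts in those of the strain experiment. At day 5 it stood at 124 ± 17.5 and 42.6 ± 12.9 CPM in Cl13 and 38.5 ± 7.32 and 17.3 ± 2.51 CPM in Arm stem-like and TD cells. Ighm, the heavy chain gene of IgM, was abundant in naive libraries, at 1189 ± 48.3 and 1186 ± 24.9 CPM, and in the stem-like groups of day 5.5, Cl13 and Arm, at 1367 ± 63.6, 1193 ± 11.8 and 1230 ± 59.8 CPM. Cd79a, its B cell partner, was at or below 7.03 CPM in those libraries. Ighm was at 532 ± 20.4, 485 ± 27.6 and 415 ± 21.3 CPM in the TD groups of day 5.5, Cl13 and Arm, and at 541 ± 47.9 and 125 ± 49 CPM in stem-like and TD cells at day 48.

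In the strain experiment Trbv13-3 and Trav14-1 led the receptor counts of all infected libraries. Reads shared alike in every library would raise Trbv13-3 in naive libraries as well, where it took at most 6.97%. Reads drawn from a close segment that leads only in infected libraries would not show there, so this stays open. Trav14-1 was not tested in this way. Separate expansions of different clones in each sample are argued against only by the pattern itself, the same pair leading in 11 of 11 libraries, and expansions that share their segments stay open. Cells of one receptor, such as transferred T cells with a transgenic receptor, are a hypothesis that was not tested, and the labels do not say that cells were transferred. The lower total of Trbv counts there remains open.

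Cirbp and Rbm3, both induced by cold, were higher and the chaperone genes Hspa8, Hsph1 and Dnaja1 lower in Cl13 than in Arm libraries of both populations, though Rbm3 lost its call in TD cells without Cl13 TD library 3 (0.56) and Dnaja1 in stem-like cells without Cl13 stem-like libraries 1 and 3 (-0.40). RNA of other cells was seen in Cl13 stem-like libraries 1 and 3. In the 3 other Cl13 libraries, 5 of 5 genes lay beyond all Arm libraries of their population. For the TD libraries among them this is the pattern itself, as the genes were chosen after it was seen. For stem-like cells it rests on library 2 alone, so a part of such RNA in the stem-like difference stays open. Cirbp was at most 25.6 CPM in the naive libraries, near the Arm level. Rbm3 averaged 71.05 CPM in naive and 162 and 224 CPM in Arm stem-like and TD libraries. Dnaja1 averaged 590 CPM in naive and 322 and 354 CPM in those Arm libraries, so neither gene was near the Arm level. Naive Hspa8 (2661 CPM) and Hsph1 (292 CPM) lay between the Arm stem-like (1889 and 220 CPM) and Arm TD levels (2754 and 363 CPM). A difference in handling, such as temperature, could give the same pattern and cannot be told apart from an effect of the infection, as the labels give no handling day.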
